A study of Macaca mulatta with 9 samples.

How the data were processed

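Total RNA from 5 rhesus macaque ES cell lines, pooled EBs and skin fibroblasts was hybridised to Affymetrix Rhesus arrays, 1 array per sample, 9 in all. The authors deposited the probe set intensity values on a linear scale, produced with Affymetrix MAS5 per the labels (version not given in the sources used here). The 2% trimmed mean of the deposited signals was 200 on each array and differed between arrays by no more than 0.01%, so the signals were taken as already scaled and were kept. The authors also deposited log2 ratios of single ES arrays over the EB array, rounded to 0.1, which per the file headers are signal log ratios with change calls (software not given in the sources used here). Detection p-values were deposited for 1 ORMES6 array, for the other 4 lines and, for 12094 probe sets, for the fibroblasts. Here they were read as Present below 0.05 and Absent above 0.065. A deposited column of detection calls, per the file headers of the EB array, was checked against the EB signals: Present and Absent probe sets differed by 0.08 in mean log2 signal, against 3.02 to 3.12 for the ES lines and 3.65 for the fibroblasts. Of 881 EB signals over 3000, 448 carried an Absent call. These EB calls were therefore used in that check only, EB detection counts as unknown, and a fold against the EBs is given as no bound. A further 136 columns of signals and detection values in the deposited tables were not used.

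The value table held 52865 probe sets. Leaving out 99 control probe sets and 3 with missing values left 52763, and no filter on level was applied. Gene symbols came from the deposited annotation, which for most probe sets names the human orthologue. Of 19772 symbols in the files 10986 were current in the reference table of macaque genes and 482 were updated. In all 40339 probe sets carried 1 symbol, 1591 of them from the description of a sequence-tagged site, and 12424 were unnamed. For the gene level (19634 genes), the probe set with the highest mean over the 7 sample values stood for the gene. Called probe sets of the same gene went in opposite directions for 23 genes against the fibroblasts and for 1 gene against the EBs.

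Signals were analysed as log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend). The 3 ORMES6 replicates, labelled as biological replicates, were averaged, so that the 5 lines were the replicates, and both differentiated samples entered the same fit as lone arrays assumed to vary as the lines do. P-values thus measure the spread between lines (4 residual degrees of freedom, median prior degrees of freedom 5.04). They were adjusted by Benjamini-Hochberg over all probe sets, or over all genes at the gene level, and called below 0.05. Lines were compared with an F test over the 7 ES arrays, whose error comes from the ORMES6 replicates, and each line was set against the other 4 in the way of a lone array. For genes called Absent on the low side, the fold was computed against a floor, the lowest signal of any Present probe set on the array. This floor is a minimum and not a detection limit, so such a fold is no strict lower bound. The fits, the scaling rule, the gene lists and the rule for naming genes were chosen before the data were examined.

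A total of 26 gene lists were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. They were pluripotency factors, epithelial and ES cell surface, fibroblast and extracellular matrix, contractile and smooth muscle, neural, cardiac and early mesoderm, blood and endothelium, endoderm and liver, trophoblast, germ cell, chromatin and DNA methylation, cell cycle and DNA replication, cyclin-dependent kinase inhibitors and p53 targets, TGF-beta, Nodal and BMP signalling, FGF signalling, WNT signalling, imprinted, MHC class I and antigen processing, MHC class II, HOX genes, X inactivation and Y-linked, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, immediate early and stress, and common reference genes. Genes named for a comparison were the 10 largest called differences in each direction with the lone array outside the range of all 7 ES arrays, up to 4 called members of each list (the 2 largest differences where none was called), and POU5F1, SOX2 and NANOG. Between lines they were the 10 genes with the smallest F test p among those with at least a 4-fold range, and called members of the X and Y, MHC class I, imprinted and pluripotency lists. The text names part of these 179 genes. EBs and fibroblasts were compared with each other by log2 differences and by list medians among 10000 random lists matched on expression (20 expression bins), with no test. The authors' deposited lists were matched by probe set.

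The fits were tested on simulated data for 52763 probe sets with 200 changed in each of 10 runs and variances drawn from the fitted prior. The Benjamini-Hochberg threshold depends on how many probe sets change, and 6291 and 1286 were called against the real fibroblasts and EBs. The shares recovered therefore describe the simulated setting and not the power of the real comparisons. For the fibroblast comparison 1.2%, 29.2%, 72%, 98% and 99.5% of changes of 2-, 4-, 8-, 32- and 256-fold were recovered and 5.1% of calls were false. For the EB comparison the shares were 1.5%, 28.5%, 71.5%, 96.8% and 99.8%, with 6.1% of calls false. For a lone line they were 0%, 9.8%, 52.5%, 92.8% and 99.8%, with 5.5% false. For the F test between lines they were 0%, 0%, 0.2%, 18.5% and 73.5%, with 8.4% false. With variances drawn from the shrunken estimates, 4-fold changes were recovered in 57%, 56.2%, 38.2% and 7% of cases for the fibroblast, EB, lone-line and F tests, and 8%, 7.3%, 8.7% and 20.1% of calls were false. In simulated lists of independently drawn genes camera called 10 of 10 changed lists and 0 unchanged ones. Correlation within lists was not simulated, whereas it was estimated at up to 0.428 in the real lists. This simulation therefore cannot show how often camera with its preset correlation calls unchanged lists in these data.

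Alternatives covered the offset (1 and 64), quantile normalization and median centring, a filter on level, the variance trend and prior, the treatment of the ORMES6 replicates (7 ES arrays as separate samples, or with the line as a random block by duplicateCorrelation with statmod 1.5.0), a 2-fold minimum, other set tests and leaving out each line and replicate. Alternatives on the level of the hybridisation spikes (27 probe sets) and on subsets of lines were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for reading tables, and figures were drawn with matplotlib 3.10.9.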

Results

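Expression was profiled in rhesus macaque embryonic stem (ES) cells and in differentiated cells with Affymetrix Rhesus genome arrays, 9 in all. ES cells are pluripotent cells derived from the early embryo. The 5 ES cell lines were ORMES6, ORMES7, ORMES9, ORMES10 and ORMES13, grown per the labels on mouse embryonic fibroblast feeder cells with FGF2, and colonies of good morphology were picked by hand. ORMES6 was measured in 3 biological replicates (A, B and C) and each of the other lines on 1 array. The differentiated samples were 1 array of pooled embryoid bodies (EBs), aggregates left to differentiate spontaneously for 30 days, and 1 array of adult skin fibroblasts. Each array gave signals for 52763 probe sets after control probe sets were left out, and 40339 of these carried 1 gene symbol, which named 19634 genes. Values are on the log2(signal + 16) scale, differences are ES minus the other sample with their standard error (SE), and the unit of replication was the cell line (5 ES lines against 1 array). The number of arrays limits the precision, and no error could be measured within the EB or fibroblast samples.

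By Pearson r the ES arrays resembled each other more than either differentiated sample. Across probe sets, which are not independent replicates, Pearson r was 0.928 to 0.977 between ES arrays, 0.904 to 0.917 between ES arrays and EBs, and 0.832 to 0.848 between ES arrays and fibroblasts. By the median absolute log2 difference the ranges overlapped for the EBs, with 0.221 to 0.428 between ES arrays, 0.422 to 0.467 to the EBs and 0.492 to 0.567 to the fibroblasts. The replicates of ORMES6 did not lie closest together throughout: replicates A and B had r = 0.977, whereas replicate C had r = 0.954 with each of them and r = 0.962 with the ORMES7 array. The median SD was 0.302 between the ORMES6 replicates and 0.341 between the 5 lines, and 54.9% of probe sets had the larger SD between lines. Replicate C carried much of the first value: without it the SDs were 0.156 and 0.359 and the share 75.2%, against 0.268 and 0.34 (58.1%) without replicate A and 0.275 and 0.341 (57.1%) without replicate B. An SD over 5 lines tends to exceed an SD over fewer replicates even at equal spread. The share to be had at equal spread was not computed. These medians and shares therefore do not show by themselves that lines varied more than replicates. Arrays also differed in the level of the hybridisation spikes, transcripts added before hybridisation: ORMES6 A, ORMES6 B and the EB array had geometric mean signals of 625.2 to 712.9 and the other 6 arrays 1022.9 to 1347. The ratio of 3' to 5' actin signal, which rises with RNA degradation and short labelled products, was 22.7 to 66.2 on the ES arrays, 7.15 on the EB array and 13.1 on the fibroblast array. The corresponding GAPDH ratio was 2.55 to 5.20 on the ES arrays, 1.61 for EBs and 2.74 for fibroblasts. For actin every ES array lay above both differentiated arrays, and for GAPDH every ES array lay above the EB array. The comparisons of ES cells with EBs and fibroblasts therefore also carry any effect of this difference, which cannot be told apart from that of cell type.

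The comparison with skin fibroblasts asked what sets the ES cells apart from a mature somatic cell. The core pluripotency regulators were far higher in the ES cells. The transcription factor SOX2 was higher by 8.08 ± 0.27 (adjusted p = 4.73e-06) and the homeobox factor NANOG by 7.84 ± 0.38 (adjusted p = 1.51e-05). POU5F1, which encodes OCT4, was higher by 7.05 ± 0.31 (adjusted p = 1.27e-05) and LIN28A, an RNA-binding protein that blocks the processing of a microRNA family, by 7.85 ± 0.34 (adjusted p = 1.27e-05). All 4 were called absent in the fibroblasts. Set against the lowest signal of any Present probe set on that array, SOX2 was 227-fold, NANOG 179-fold and LIN28A 202-fold higher. Absent probe sets there averaged above that level (mean log2 4.86), so these folds are not strict lower bounds. The fibroblasts in turn had high levels of MMP3, a matrix-degrading protease (ES minus fibroblasts -8.20 ± 0.45, adjusted p = 2.44e-05), and of the neutrophil-attracting chemokine CXCL8 (-8.10 ± 0.40, adjusted p = 1.73e-05). In all, 3400 probe sets were higher and 2891 lower in the ES cells at an adjusted p under 0.05, and 6286 of these 6291 had the fibroblast value outside the range of all 7 ES arrays.

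The 10 genes with the largest excess in ES cells were FLJ16517, SOX2, RBPMS2, LIN28A, NANOG, KAL1, OTX2, MYCN, PTPRZ1 and SPP1, with differences of 7.12 to 8.11. OTX2 is a homeobox factor of the epiblast and forebrain, MYCN a growth-promoting transcription factor, KAL1 the secreted protein anosmin and SPP1 osteopontin. Among the pluripotency factors, 21 of 33 measured members were higher in ES cells and 2 lower (22 and 2 adjusted over the list alone). Their median difference was 3.42, and the list moved up as a set (adjusted p = 1.4e-11, and adjusted p = 0.205 with an estimated correlation). The epithelial and ES cell surface list had 11 of 21 members higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 2.52 (adjusted p = 6.71e-06, and adjusted p = 0.464 with an estimated correlation). Its median was 1.61 to 2.03 on the arrays of ORMES6 and ORMES7 and 3.0 to 3.34 in ORMES9, ORMES10 and ORMES13. Its leading members were the adhesion molecule EPCAM (6.88 ± 0.82), the sialomucin PODXL (6.19 ± 0.62), the splicing regulator ESRP1 (6.06 ± 0.80) and the surface antigen CD24 (5.65 ± 0.25).

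Genes of cell division formed the most uniform group. Of 40 cell cycle and DNA replication genes, 36 were higher in ES cells and 0 lower (37 and 0 adjusted over the list alone), with a median difference of 2.83 (adjusted p = 3.45e-22). This list alone held its call with an estimated correlation (adjusted p = 0.0446). MCM3, MCM5 and MCM2, subunits of the replicative helicase, differed by 4.85 ± 0.23, 4.05 ± 0.32 and 3.86 ± 0.20, and ORC1 of the origin recognition complex by 4.16 ± 0.34. Chromatin and DNA methylation genes followed, with 18 of 27 higher and 0 lower (20 and 0 adjusted over the list alone; adjusted p = 5.2e-09, and adjusted p = 0.263 with an estimated correlation). They were led by the de novo DNA methyltransferase DNMT3B (7.03 ± 0.28), the remodeller CHD7 (4.16 ± 0.45), the Polycomb methyltransferase EZH2 (4.15 ± 0.26) and its partner JARID2 (3.98 ± 0.27). The cyclin-dependent kinase inhibitors and p53 targets went the other way, with 4 of 21 lower and 1 higher, unchanged in number over the list alone (adjusted p = 0.00906, and adjusted p = 0.383 with an estimated correlation). The lower members were GDF15 (-4.23 ± 0.52), the inhibitor p21 encoded by CDKN1A (-4.12 ± 0.40), CDKN2C (-3.85 ± 0.55) and the death receptor FAS (-2.90 ± 0.43).

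The 10 largest deficits in ES cells were in MMP3, CXCL8, BF, NR4A3, PTGS1, CXCL6, FGL2, KBTBD10, SRGN and GPNMB, with differences of -8.20 to -7.57. BF is a complement protease, PTGS1 a prostaglandin synthase and CXCL6 another chemokine. In the fibroblast and extracellular matrix list 14 of 35 members were lower and 1 higher (15 and 1 adjusted over the list alone), with a median of -2.76 (adjusted p = 1.4e-11, and adjusted p = 0.395 with an estimated correlation). Examples were the surface protease FAP (-7.49 ± 0.71), the mesenchymal homeobox factor PRRX1 (-5.96 ± 1.06), the collagen cross-linking enzyme LOX (-5.59 ± 0.88) and IGFBP7 (-5.40 ± 0.90). This list was not equally low in all lines: its median against the fibroblasts was -3.80 to -3.22 on the arrays of ORMES6 and ORMES7 and -1.92 to -1.49 in ORMES9, ORMES10 and ORMES13. The contractile and smooth muscle list had 9 of 16 lower and 1 higher, also over the list alone (median -1.52, adjusted p = 2.57e-05, and adjusted p = 0.361 with an estimated correlation). Smooth muscle actin ACTA2 was at -3.71 ± 0.57 and tropomyosin TPM2 at -3.28 ± 0.40. MHC class I and antigen processing genes were lower in 6 of 14 cases and higher in 0 (9 and 0 adjusted over the list alone; median -1.79, adjusted p = 5.2e-06, and adjusted p = 0.205 with an estimated correlation). These included HLA-E (-4.33 ± 0.67), the peptide loading factor TAPBP (-3.39 ± 0.46) and the immunoproteasome subunit PSMB9 (-3.70 ± 0.58). Of the immediate early and stress genes 5 of 23 were lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.00737, and adjusted p = 0.464 with an estimated correlation). The list median was -0.85 to -0.59 on the arrays of ORMES6 and ORMES7, 0.01 in ORMES9, -0.44 in ORMES10 and -0.30 in ORMES13. The phosphatase DUSP1 was at -3.44 ± 0.34 and TXNIP at -2.97 ± 0.53. Over the 7 ES arrays the median of the contractile list ran from -2.12 to -1.05, that of the MHC class I list from -2.16 to -1.10 and that of the kinase inhibitors and p53 targets from -0.42 to -0.08.

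Several lists held members that moved apart, and these lists were not called as sets. FGF signalling had 9 of 21 members higher and 4 lower (median 1.22, adjusted p = 0.305). FGF13 (5.19 ± 0.35) and the receptor FGFR3 (4.37 ± 0.60) were higher in ES cells, and FGF7 (-7.24 ± 0.98) and FGF2 (-3.89 ± 0.39) higher in fibroblasts. In TGF-beta, Nodal and BMP signalling 12 of 33 were higher and 5 lower (median 0.97, adjusted p = 0.511), with the Nodal inhibitor LEFTY2 at 6.0 ± 0.80 and the BMP antagonist GREM1 at -6.48 ± 0.89. WNT signalling had 7 of 28 higher and 5 lower (adjusted p = 0.924), with the receptor FZD8 at 3.14 ± 0.52 and the secreted DKK3 at -4.83 ± 0.36. The imprinted list had 2 of 26 higher and 3 lower (adjusted p = 0.475), among them MEST at 5.27 ± 0.40 and SGCE at -4.22 ± 0.76. Trophoblast genes had 5 of 22 higher and 3 lower (adjusted p = 0.785), with EOMES at 4.63 ± 0.39 and KRT7 at -5.25 ± 0.79. For the WNT, imprinted, trophoblast and common reference lists the set test pointed down while the median or the mean was above 0. Some markers of early lineages were higher in the ES cells than in fibroblasts. They were 7 of 30 neural genes (adjusted p = 0.0786), including SYT1 (4.60 ± 0.36) and NES (2.73 ± 0.29), and 5 of 24 cardiac and early mesoderm genes (adjusted p = 0.0786), including the primitive streak factor T (3.84 ± 0.59). Of the endoderm and liver genes 3 of 32 were higher and 1 lower (adjusted p = 0.344), with FOXA3 at 4.59 ± 0.39. Blood and endothelium genes had 4 of 26 higher and 2 lower (adjusted p = 0.953), with the receptor TEK at 4.41 ± 0.56.

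No member of the HOX genes (38 measured, median 1.15, adjusted p = 0.171), the cytosolic ribosomal proteins (35, median 0.29, adjusted p = 0.267) or the germ cell genes (15, median 0.25, adjusted p = 0.827) passed the limma test against the fibroblasts. The HOX median was 0.15 to 0.49 on the arrays of ORMES6 and ORMES7, 1.02 in ORMES9, 1.29 in ORMES10 and 2.25 in ORMES13. Few members did in glycolysis (3 of 19 higher, 2 lower, adjusted p = 0.338) and oxidative phosphorylation (2 of 25 higher, 1 lower, adjusted p = 0.785). The same held for MHC class II (1 of 11 higher, 1 lower, adjusted p = 0.953), the common reference genes (1 of 15 higher, 1 lower, adjusted p = 0.977) and the X inactivation and Y-linked list (1 of 9 higher, 0 lower, adjusted p = 0.0786). The median difference over all probe sets was 0.19, against which the list medians are to be read. Calls higher in ES cells were 54% of the total, but the balance turned to 45.2% with an offset of 64, 47.5% with quantile normalization and 35.9% (2318 higher, 4147 lower) when each array was centred on its median. With the ES arrays of the same spike level as the fibroblast array there were 3827 higher and 3120 lower probe sets, and 3877 and 3032 with spike level as a covariate. Requiring a change beyond 2-fold left 840 higher and 935 lower.

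**Figure D1:**
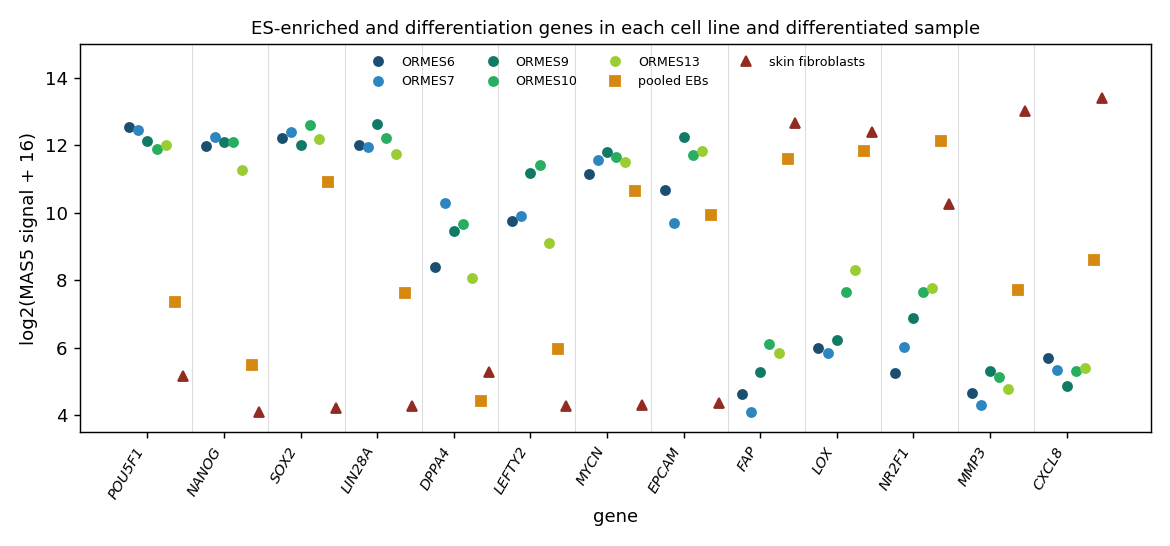
Level of 13 genes on the log2(MAS5 signal + 16) scale (vertical axis) in each ES line (circles; ORMES6 is the mean of 3 replicates, the others 1 array), in pooled EBs (squares) and in skin fibroblasts (triangles). NANOG lies at 11.27 to 12.25 in the 5 lines, 5.47 in EBs and 4.10 in fibroblasts, whereas SOX2 remains at 10.92 in EBs against 4.21 in fibroblasts.

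The comparison with the EBs asked which genes are lost or gained when ES cells differentiate spontaneously. NANOG (6.47 ± 0.38, adjusted p = 0.00073) and POU5F1 (4.86 ± 0.31, adjusted p = 0.00073) were higher in ES cells. So were the nuclear protein DPPA4 (4.76 ± 0.76, adjusted p = 0.0147), LIN28A (4.49 ± 0.34, adjusted p = 0.00139) and LEFTY2 (4.31 ± 0.80, adjusted p = 0.0228). SOX2, which also marks neural progenitors, differed by 1.37 ± 0.27 (adjusted p = 0.0273), and this call was lost without ORMES7 or without ORMES10 and with spike level as a covariate. The EBs had higher levels of FAP (-6.41 ± 0.71, adjusted p = 0.00444) and of the cytokine IL1B (-6.08 ± 0.57, adjusted p = 0.00235). They also had higher levels of the nuclear receptor NR2F1 (-5.40 ± 0.87, adjusted p = 0.0152) and of the radial glia lipid carrier FABP7 (-5.39 ± 0.83, adjusted p = 0.0135). There were 481 probe sets higher and 805 lower in the ES cells, each with the EB value outside the range of all 7 ES arrays, and with an offset of 1 the balance turned to 519 higher and 444 lower. The remaining genes among the 10 largest on either side were LCK, NFE2L3, FLJ20273, VRTN and LYCAT, higher in ES cells, and OGN, COL8A1, PTX3, DKFZp434L142, EBF and LOX, higher in EBs. LCK, FLJ20273 and DKFZp434L142 lost the call without ORMES10, and LCK also with an offset of 64 and DKFZp434L142 with an offset of 1 and without ORMES9.

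As against the fibroblasts, the dividing and undifferentiated state stood out, with smaller differences. Cell cycle and DNA replication genes were higher in 20 of 40 cases and lower in 0 (30 and 0 adjusted over the list alone), with a median of 1.41 (adjusted p = 2.79e-17, and adjusted p = 0.0717 with an estimated correlation). Examples were ORC1 (2.58 ± 0.34), MCM5 (2.54 ± 0.32) and the mitotic checkpoint kinase BUB1 (2.12 ± 0.23). Of 33 pluripotency factors 13 were higher and 0 lower (17 and 0 adjusted over the list alone; median 1.51, adjusted p = 4.52e-13, and adjusted p = 0.124 with an estimated correlation). Chromatin and DNA methylation genes were higher in 8 of 27 cases and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 7.98e-07, and adjusted p = 0.329 with an estimated correlation). They were led by DNMT3B (3.87 ± 0.28), the helicase HELLS (2.58 ± 0.38), JARID2 (2.54 ± 0.27) and the architectural factor HMGA1 (2.01 ± 0.23). The epithelial and ES cell surface list had 2 of 21 higher and 6 adjusted over the list alone (adjusted p = 3.31e-04, and adjusted p = 0.552 with an estimated correlation). The higher members were the tight junction protein CLDN6 (2.43 ± 0.45) and the integrin ITGA6 (2.28 ± 0.30). Its median against the EBs was -0.03 to 0.34 on the arrays of ORMES6 and ORMES7 and 1.40 to 1.62 in ORMES9, ORMES10 and ORMES13. FGF signalling had 2 of 21 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 0.00112, and adjusted p = 0.124 with an estimated correlation). These were DUSP6 (1.93 ± 0.34), which dampens ERK signalling, and the transcription factor ETV4 (2.29 ± 0.49), whose call was lost with an offset of 64 and without ORMES7 or without ORMES10.

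The EBs expressed neural and mesenchymal genes. In the neural list 10 of 30 members were lower in ES cells and 1 higher (14 and 2 adjusted over the list alone), with a median of -1.67 (adjusted p = 2.36e-07, and adjusted p = 0.124 with an estimated correlation). They included the neuronal migration protein DCX (-4.43 ± 0.55) and the neuronal RNA-binding protein ELAVL4 (-3.74 ± 0.47), and MEIS1 (-4.85 ± 1.05) and ZIC1 (-4.52 ± 1.06), whose calls were lost with an offset of 1 and without ORMES9 or ORMES10, among other settings. The fibroblast and extracellular matrix list had 6 of 35 lower and 0 higher (11 and 0 adjusted over the list alone; median -1.96, adjusted p = 1.6e-10, and adjusted p = 0.444 with an estimated correlation). LOX was at -5.04 ± 0.88 and the mesenchymal factor TWIST2 at -2.75 ± 0.46. Its median against the EBs was -2.82 to -2.38 on the arrays of ORMES6 and ORMES7 and -1.73 to -1.0 in the other 3 lines. HOX genes, which pattern the body axis, were lower in 2 of 38 cases and 5 adjusted over the list alone (median -1.49, adjusted p = 7.59e-06, and adjusted p = 0.469 with an estimated correlation). The list median against the EBs was -2.32 to -1.78 on the arrays of ORMES6 and ORMES7, -1.39 in ORMES9, -1.61 in ORMES10 and -0.65 in ORMES13. The members were HOXA7 (-3.37 ± 0.61), whose call was lost without ORMES10, and HOXA4 (-3.04 ± 0.45), and both calls were lost with an offset of 1. Cyclin-dependent kinase inhibitors and p53 targets were lower in 2 of 21 cases and 5 adjusted over the list alone (adjusted p = 0.0108, and adjusted p = 0.413 with an estimated correlation), with CDKN1A at -3.27 ± 0.40. In glycolysis 4 of 19 genes were lower and 1 higher (6 and 4 adjusted over the list alone; adjusted p = 0.0351, and adjusted p = 0.582 with an estimated correlation). The lower genes included ALDOC (-2.12 ± 0.33) and PKM (-1.95 ± 0.28), and the list's call was lost without ORMES6. Cytosolic ribosomal proteins were called higher in ES cells as a set (4 of 35 higher, 9 higher and 1 lower adjusted over the list alone; median 0.38, adjusted p = 0.0015, and adjusted p = 0.469 with an estimated correlation), a direction that turned with quantile normalization of the arrays. Over the 7 ES arrays the list medians ran from 0.08 to 0.60 for the ribosomal proteins, from 0.32 to 1.09 for chromatin genes, from -1.15 to -0.32 for the kinase inhibitors and p53 targets and from -0.62 to -0.22 for glycolysis.

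The other lists were not called against the EBs. The imprinted list had 1 of 26 members higher and 2 lower (median -0.71, adjusted p = 0.0597), with MEST at -2.18 ± 0.40, so that MEST was higher in EBs and lower in fibroblasts than in ES cells. Contractile and smooth muscle genes had 0 higher and 2 lower of 16 (adjusted p = 0.0545), with ACTA2 at -3.05 ± 0.57, a call lost without ORMES9. TGF-beta, Nodal and BMP signalling had 2 of 33 higher and 5 lower (adjusted p = 0.367), with TGFB2 at -3.50 ± 0.63. WNT signalling had 3 of 28 higher and 2 lower (adjusted p = 0.72), with the transcription factor TCF7 at 3.03 ± 0.48 and DKK3 at -2.72 ± 0.36. Cardiac and early mesoderm genes had 2 of 24 higher and 2 lower (adjusted p = 0.359), with T at 3.58 ± 0.59 and the intermediate filament DES at -2.13 ± 0.35. Immediate early and stress genes had 1 of 23 higher and 2 lower (adjusted p = 0.123), trophoblast genes 2 of 22 higher (adjusted p = 0.625) and endoderm and liver genes 2 of 32 higher (adjusted p = 0.165). Blood and endothelium genes had 1 of 26 higher and 1 lower (adjusted p = 0.72), common reference genes 1 of 15 higher (adjusted p = 0.16) and oxidative phosphorylation genes 1 of 25 higher (adjusted p = 0.902). No member passed in MHC class I and antigen processing (14 measured, adjusted p = 0.902), MHC class II (11, adjusted p = 0.957), the germ cell list (15, adjusted p = 0.419) or the X inactivation and Y-linked list (9, adjusted p = 0.189).

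The size of the EB counts depended on single arrays and on which ES arrays gave the error. With ORMES6 A and B as the only ES arrays, the error was the spread between these replicates and not between lines. The counts of that fit are therefore not comparable with the others. Without ORMES10, ORMES7, ORMES9 or ORMES6 replicate C there were 151, 236, 242 and 267 probe sets higher in ES cells, and without ORMES10, ORMES9 or ORMES7 there were 349, 440 and 474 lower. With the ES arrays of the EB array's spike level, ORMES6 A and B, the counts were 4420 higher and 5111 lower, with the high-spike ES arrays 820 and 1153, and with spike level as a covariate 583 and 776. A change beyond 2-fold was called for 24 higher and 84 lower probe sets.

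A group of genes set the ES cells apart from both differentiated samples. A total of 365 probe sets were higher and 337 lower in ES cells in both comparisons, and 22 were called in opposite directions. At the gene level 415 genes were higher in both, among them NANOG, POU5F1, LIN28A, SOX2, LEFTY2, DNMT3B, JARID2, ORC1, MCM5, FOXA3 and T, and 253 were lower in both, among them FAP, LOX, ACTA2, TPM2, DKK3 and CDKN1A. The call against the EBs was lost without ORMES10 for TPM2 and without ORMES7 or ORMES10 for FOXA3. Independent lists of these lengths would share 31 higher and 44.1 lower probe sets. Both comparisons use the same ES arrays. The covariance of the log2 differences was 0.383, against 0.0302 from the shared ES lines alone. When the lines were split so that each comparison had its own (20 splits, 3 lines for one and 2 for the other), the overlap had a median of 24.5 higher (0 to 513) and 25 lower (0 to 572) probe sets, where independent lists would share a median of 0.429 and 1.57. In several splits the EB comparison called 0 probe sets in either direction, so the overlap there could only be 0. These splits also enter the medians. Without ORMES10, ORMES7, ORMES9 or ORMES6 replicate C the overlap was 120, 179, 186 and 209 probe sets higher and 152, 200, 183 and 222 lower.

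**Figure D2:**
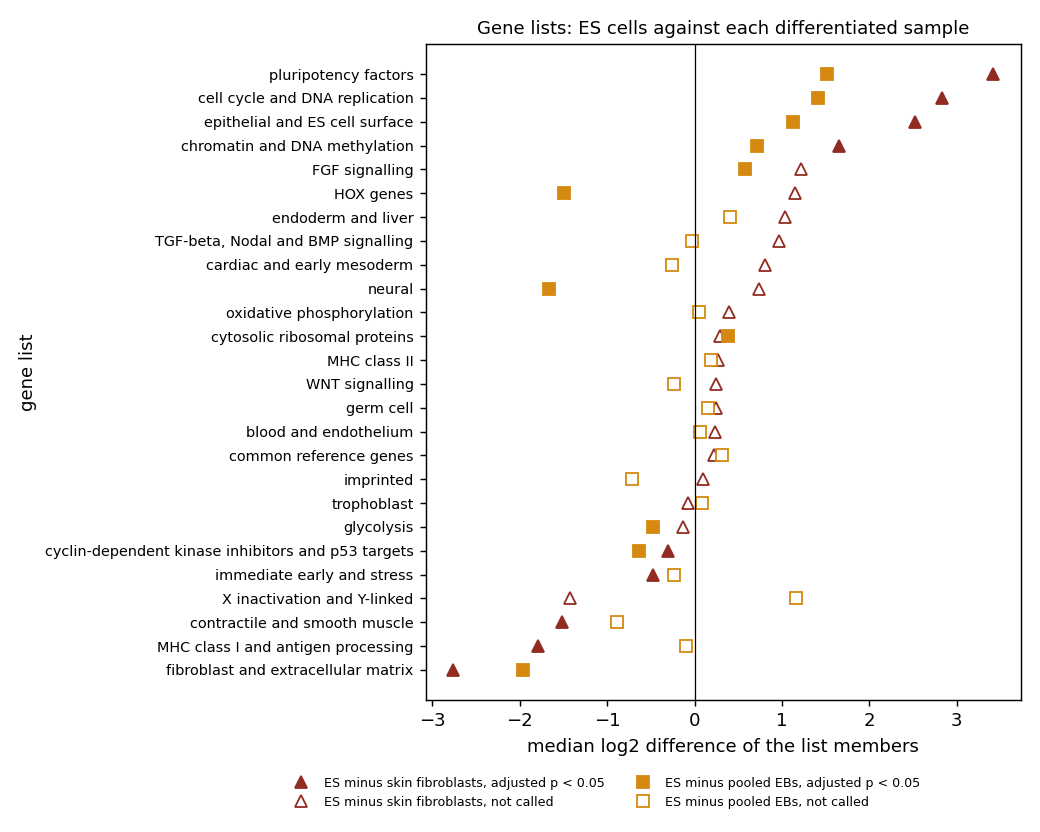
Median log2 difference of the measured members (horizontal axis) for each of 26 gene lists, ES cells minus skin fibroblasts (triangles) and ES cells minus pooled EBs (squares), with filled symbols for lists called by camera with its preset correlation. Pluripotency factors (3.42 and 1.51) and cell cycle genes (2.83 and 1.41) lie to the right in both comparisons and the matrix list to the left (-2.76 and -1.96), while neural genes (0.74 and -1.67) lie on opposite sides. So do the HOX genes (1.15 and -1.49), with medians of 0.15 to 2.25 against the fibroblasts over the 7 ES arrays and no list call there. The cytosolic ribosomal proteins, filled for EBs, turned direction with quantile normalization.

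Set directly against each other, the EB and fibroblast arrays differed most in patterning genes. This comparison is of 1 array with 1 array and has no replicate check. The HOX genes had a median EB minus fibroblast difference of 2.85, which lay at percentile 100 of 10000 random lists of the same size and mean expression (random median 0.36), and 25 of 38 were at least 4-fold higher in EBs. Neural genes had a median of 2.45 (percentile 100) with 17 of 30 at least 4-fold higher. Cell cycle genes (1.54), cardiac and early mesoderm genes (1.26), chromatin genes (1.13), pluripotency factors (1.05) and TGF-beta, Nodal and BMP signalling genes (0.97) were also at percentile 100. MHC class I genes lay at the other end, with a median of -1.81 (percentile 0) and 5 of 14 at least 4-fold lower in EBs. The X inactivation and Y-linked list lay there too (-1.76, percentile 0, 4 of 9 at least 4-fold lower). The Y-linked DDX3Y, EIF1AY and USP9Y read 5.01, 5.38 and 4.39 in EBs and 11.68, 10.73 and 9.37 in fibroblasts. Among the ES lines only ORMES7 read them high (11.79, 11.05 and 9.36). This list thus separates samples with and without Y-linked expression and is not read as a difference of differentiation. Over all genes the median was 0.20, with 1127 genes at least 4-fold higher in EBs and 578 at least 4-fold higher in fibroblasts.

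Genes that differed between the 5 ES lines included genes of the matrix, imprinted genes and a Y-linked gene, with no gene list tested between lines. LUM and DCN, small matrix proteoglycans, COL3A1, a fibrillar collagen, HAPLN1, a link protein of cartilage matrix, and TGFBI were low in ORMES6 and ORMES7 and high in ORMES9, ORMES10 and ORMES13. LUM read 4.70 and 4.98 in the first pair and 10.46, 11.40 and 12.37 in the other 3 lines (adjusted p = 0.0173). HAPLN1 read 4.19 and 4.29 against 10.13, 10.28 and 11.52 (adjusted p = 0.0173), and COL3A1 7.02 and 8.34 against 11.06, 12.22 and 12.74 (adjusted p = 0.0173). DCN and TGFBI followed with line ranges of 7.04 and 5.87 (adjusted p = 0.0252 each). The same split was seen in genes outside the matrix. FGB, the fibrinogen beta chain made by the liver, read 4.59 and 4.22 against 8.58, 10.18 and 11.18 (adjusted p = 0.0224). It was also seen in the endoderm and blood homeobox factor HHEX (8.82 and 7.30 against 11.81, 11.61 and 10.81, adjusted p = 0.0319) and the imprinted growth regulator DLK1 (6.08 and 7.63 against 10.76, 11.75 and 12.34, adjusted p = 0.0382), a call lost with an offset of 1 and without a variance trend.

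The probe sets with the highest signal for the imprinted genes SNRPN, IPW and PEG3 were near background in ORMES9, while MEST, also imprinted, read 9.92 there and 9.60 to 10.63 in the other lines. SNRPN, in the Prader-Willi region, read 4.67 in ORMES9 and 12.71 to 12.99 in the other lines (adjusted p = 0.0224), the noncoding IPW of the same region 5.08 against 10.46 to 11.01 (adjusted p = 0.0177), and PEG3 4.81 against 9.48 to 10.92 (adjusted p = 0.0252). NDN, also of that region, was low in both ORMES9 (4.48) and ORMES10 (4.31) and read 8.72, 6.90 and 8.37 in ORMES6, ORMES7 and ORMES13 (adjusted p = 0.0382), a call lost without ORMES6 replicate B. DDX3Y, a Y-linked RNA helicase, read 11.79 in ORMES7 and 4.74 to 4.99 in the other lines (adjusted p = 0.0382), with 5.01 in EBs and 11.68 in fibroblasts, a call lost with an offset of 1. In the comparison of each line with the other 4, the Y-linked EIF1AY (4.55 ± 0.38, adjusted p = 0.0194) and USP9Y (4.53 ± 0.40, adjusted p = 0.0218) were likewise higher in ORMES7, and CAP1, an actin-binding protein, was lower in ORMES9 (-4.04 ± 0.26, adjusted p = 0.00268). EIF1AY, USP9Y and CAP1 were chosen after their values were seen, and EIF1AY was not called by the F test over the lines (adjusted p = 0.0929). The low CAP1 probe sets were designed to the same target. A sequence variant in ORMES9 therefore cannot be told apart from lower expression of CAP1. These tests of 1 line against 4 called 20 probe sets over the 5 lines (1 in ORMES6, 7 in ORMES7, 10 in ORMES9, 1 in ORMES10 and 1 in ORMES13). With 4 ES lines, the lowest counts against the differentiated samples came without ORMES10, at 2586 higher and 2369 lower for fibroblasts and 151 and 349 for EBs.

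The F test over the lines called 55 probe sets (39 genes at the gene level) and 5247 at an unadjusted p under 0.05. In 35 of the 55 probe sets ORMES9, ORMES10 and ORMES13 were all above ORMES6 and ORMES7, and in 3 all below. Its error rests on the ORMES6 replicates alone, so the count hinged on them: 0 probe sets were called by limma without replicate A and 0 without replicate B (2433 and 2382 at an unadjusted p under 0.05), and 8364 without replicate C. The gene-level test kept its call for 13 of the 13 named genes without replicate A, 12 without replicate B (NDN lost it, adjusted p = 0.073) and 13 without replicate C. The probe set count was 156 with arrays centred on their median, 130 for probe sets above the median level and 3 without a variance trend.

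**Figure D3:**
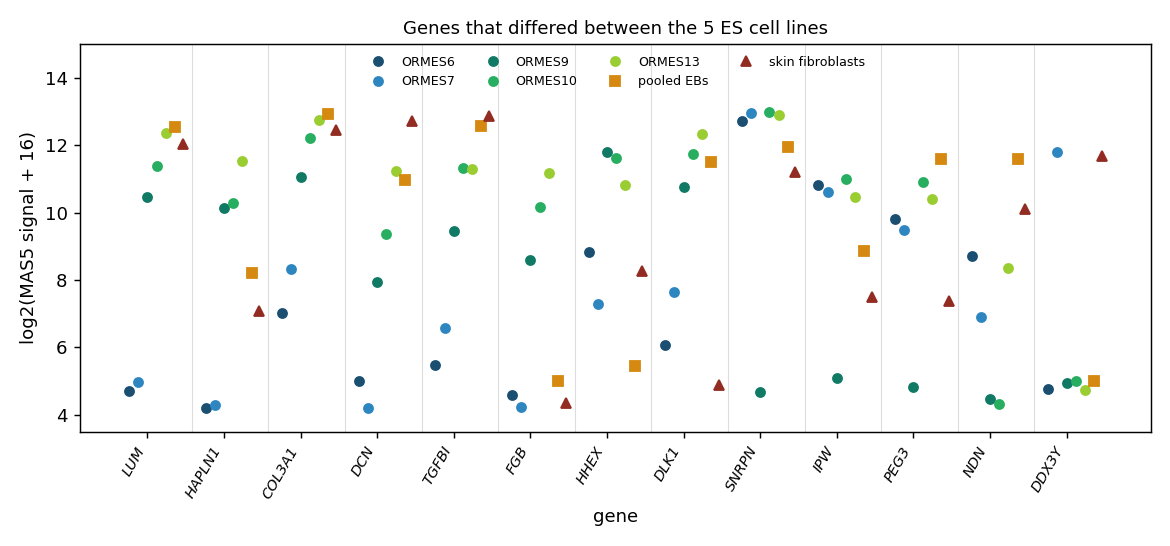
Level of 13 genes that differed between ES lines on the log2(MAS5 signal + 16) scale (vertical axis), with circles for the 5 lines (ORMES6 is the mean of 3 replicates, the others 1 array), squares for pooled EBs and triangles for skin fibroblasts. LUM, HAPLN1, COL3A1, DCN, TGFBI, FGB, HHEX and DLK1 are higher in ORMES9, ORMES10 and ORMES13, SNRPN, IPW and PEG3 lie at 4.67 to 5.08 in ORMES9, and DDX3Y is at 11.79 in ORMES7 and 11.68 in fibroblasts.

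The authors deposited lists of probe sets from comparisons of single ES arrays with the EB array. In the authors' deposited table of 367 probe sets increased in ORMES6, 99.2% were higher in the mean of the 5 lines than in EBs and 172 were among the 481 called. In the authors' deposited table of genes increased in ORMES6 A, 5408 probe sets had values here, 86.3% were higher in the mean of the lines and 450 were called. In each authors' deposited table for ORMES7, ORMES9, ORMES10 and ORMES13 (4066, 4766, 4267 and 3667 probe sets), 98.3%, 97.9%, 98.5% and 96.3% were higher and 457, 461, 456 and 447 called. In a second authors' deposited table of 3200 probe sets, of which 3064 were lower in ORMES6 A by the deposited ratio, 3196 had values here, 93% were lower in the mean of the lines and 356 were among the 805 called. No probe set of these lists was called in the opposite direction. The lists were drawn from the same arrays and are not independent of these values.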

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

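All tests of explanations in this part were chosen after the results were seen. Lines were screened for a value far from those of the other 4 (Dixon's test, gap to the nearest line over 0.71 of the range, and the 95% critical value for 7 among the ES arrays), which chance gives in about 5% of genes. Of 179 named genes 18 had such a line. Of these, 4 were among the 13 genes named for a difference between lines, to which that chance share does not apply, and 14 among the other 166.

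The first pattern is the set of 35 probe sets higher in ORMES9, ORMES10 and ORMES13 than in ORMES6 and ORMES7, of which 4 were over 3 log2 units lower in ORMES6 alone or ORMES7 alone than in each other line. Differentiated cells among the picked ES cells could raise such genes, but 21 of the 35 (18 of 31 without those 4) were over 1 log2 unit above the skin fibroblasts and 16 (13 of 31) over 1 unit above the EBs, while 8 and 11 were over 1 unit below, which argues against cells like either sample as the cause of all of it. For the 14 probe sets not above the fibroblasts, the fibroblast share needed had quartiles of 22.9% and 77.3%, whereas the 50 most abundant fibroblast probe sets low in ORMES6 and ORMES7 allowed a median of 0.621% (upper quartile 2.88%), with CXCL8 at 13.42 in fibroblasts and 4.85 to 5.38 in the 3 lines. For the 19 not above the EBs the share needed had quartiles of 26.9% and 81.2% and a lowest value of 11.8%. The EBs' abundant probe sets allowed a median of 9.47% (upper quartile 18.3%). IL1B read 11.03 in EBs and 4.90 to 5.74 in the 3 lines. These values argue against cells like the EB pool as a whole for most of the 19, but not for those needing least. All 35 probe sets were chosen for a difference between these same lines. That choice raises the share needed for either sample and weakens both arguments. Single cell types of the EBs, differentiated cells of another kind, carried-over mouse feeder cells and a difference between the donor embryos of the lines were not tested and stay open.

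The second pattern is the low reading of the highest probe sets of SNRPN (4.67), IPW (5.08) and PEG3 (4.81) in ORMES9, where the other 4 lines read 12.71 to 12.99, 10.46 to 11.01 and 9.48 to 10.92. Weak hybridisation of that array is argued against, since 0.0643% of the probe sets detected in the other 4 lines (11 of 17102) were over 3 log2 units lower in ORMES9. A sequence variant under a single probe set is argued against for SNRPN, since its other probe set over 7 in each other line was 7.32 below the lowest of them in ORMES9. Of 4 weaker detected ones, 1 read 6.82 to 8.20 in the other lines and 5.16 in ORMES9, which is 1.66 below the lowest. The rest lay -0.22 to 0.67 below and are too near background to decide. Whether the probe sets share sequence was not tested. For IPW and PEG3, 0 other probe sets had that much signal, so such a variant may contribute and cannot be told apart from lost expression, although the weaker PEG3 probe set was also lowest in ORMES9 (4.91 against 6.88 to 8.59). MAGEL2 of the Prader-Willi region (4.39 against 7.42 to 9.09) and the imprinted SGCE (5.13 against 6.81 to 7.45) and ATP10A (4.18 against 5.44 to 5.65) were also lowest in ORMES9. These genes were named for that. ATP10A is near background in all lines, read 4.83 on ORMES6 A alone and was not called by the F test (adjusted p = 0.525). Other imprinted genes were not lowest there, such as GRB10 (11.55 against 11.21 to 11.54). A line-specific change of imprinting remains an untested hypothesis.

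Lines with a value far from the others were also found for Y-linked genes, with ORMES7 at 11.79 for DDX3Y (others 4.74 to 4.99) and at 11.05 for EIF1AY (others 6.24 to 6.69). ORMES7 stood out with DUSP1 at 9.64 (others 8.85 to 9.07). ORMES13 stood out with NANOG at 11.27 (others 11.98 to 12.25), HOXA7 at 6.0 (4.27 to 4.46), CDKN2C at 6.84 (5.46 to 5.64), GDF15 at 5.87 (4.43 to 4.83) and FGL2 at 5.07 (4.09 to 4.32). ORMES6 enters these ranges as the mean of its replicates, and replicate C alone read 6.37 for CDKN2C and 5.30 for GDF15. Neither of these genes was called between lines by the F test (adjusted p = 0.67 and 0.546). ORMES10 stood out with DMC1 at 6.26 (5.32 to 5.58) and PTX3 at 5.96 (4.73 to 5.01). ORMES6 stood out with CDKN1B at 8.91 (8.16 to 8.34) and RUNX1 at 4.78 (6.20 to 6.60), and ORMES9 with RBP4 at 4.74 (4.10 to 4.15). The F test did not call DUSP1 (adjusted p = 0.502), HOXA7 (0.175), FGL2 (0.398), DMC1 (0.76) or CDKN1B (0.429) between lines either. For DMC1, ORMES6 A alone read 5.91. FGL2 and RBP4 read near background in all lines. Among the 7 ES arrays, the 3' to 5' actin ratio of ORMES6 A was 22.68, with the others at 49.34 to 66.16.

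For some genes the lines fell on both sides of a differentiated sample, by more than 1 log2 unit each way, with the difference between lines tested by the F test. HAPLN1 ranged over 7.32 between lines, on both sides of EBs and fibroblasts (adjusted p = 0.0173). SNRPN ranged over 8.32 (adjusted p = 0.0224) and IPW over 5.92 (adjusted p = 0.0177), likewise around both samples. PEG3 ranged over 6.10 around the fibroblasts (adjusted p = 0.0252), and the cardiac actin ACTC1 over 3.28 around the EBs (adjusted p = 0.0348).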

How the results depend on the processing

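No paired analysis was possible because the EBs and the fibroblasts are 1 array each and share no replicate numbers with the lines. The alternatives on spike level and on subsets of lines were chosen after the results were seen. No alternative addressed the 3' to 5' actin ratio, which was higher on every ES array than on both differentiated arrays. Against the fibroblasts, the counts stayed within 1.5 times under each alternative but the 2-fold minimum (840 higher, 935 lower), and 83 to 106 of the 106 named gene results kept direction and side of the threshold in each. Against the EBs 20 of 86 did so with the 2-fold minimum (24 higher, 84 lower probe sets; 20 and 25 in both comparisons), 55 without ORMES10 and 62 to 85 in the others. The offset and the filter on level moved these counts. With an offset of 1 the EB comparison gave 519 higher and 444 lower, which turned the balance of 481 and 805, and with 64 it gave 504 and 1330. Probe sets above the median level gave 911 higher, and 644 and 523 in both comparisons. The offset also moved the median SD of the ORMES6 replicates (0.492 and 0.154) and of the lines (0.569 and 0.176), and the share in the authors' list of 3200 probe sets (95.5% and 91.8%), by construction. Quantile normalization gave 96.8% for the ORMES7 list and 97% for the ORMES9 list.

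Leaving out single lines or replicates gave 151 to 643 higher and 349 to 966 lower probe sets against EBs, 120 to 483 and 152 to 421 in both comparisons, 0 to 8364 between lines, and median SDs of 0.156 to 0.275 for ORMES6 and 0.34 to 0.359 between lines. The F test gave 156 with median centring, 130 above the median level and 3 without a variance trend. The EB comparison gave 4420 and 5111 with the low-spike ES arrays, 820 higher with the high-spike ones, and 767 and 1764 with ORMES6 and ORMES7 only, where both comparisons shared 552 and 842. The fit with the low-spike ES arrays took its error from ORMES6 A and B alone, so its counts also reflect another error term. Beyond that, the cause of these shifts was not tested. Lists called fell from 9 to 1 (fibroblasts) and from 11 to 0 (EBs, 4 at an unadjusted p under 0.05) with camera's estimated correlation, and 7 were called for EBs with fry. With quantile normalization RPS12 (0.00) and RPS16 (-0.01) lost their difference from EBs, and the ribosomal protein list turned to lower in ES cells (direction -1, not called). The common reference genes turned to higher than in fibroblasts with fry (direction 1, called). Filtering on a Present call on at least 1 array was not run, since calls of all arrays were not usable.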

Other observations

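The tests in this part, and the genes named, were chosen after the values were seen. Beyond the matrix genes, the probe sets high in ORMES9, ORMES10 and ORMES13 included the following genes at levels above both differentiated samples. No gene list was tested between lines. The mean of these lines was 10.84 for the apolipoprotein APOA1 (EBs 8.72, fibroblasts 4.22), 9.58 for the thyroxine carrier TTR (6.82 and 8.30), 10.30 for HAND1, a factor of trophoblast and mesoderm (8.58 and 5.31), 10.39 for the apelin receptor APLNR (7.23 and 4.97) and 9.13 for ALAS2, the erythroid enzyme of haem synthesis (5.34 and 5.97). The receptor tyrosine kinase KIT was at 11.34 (9.48 and 4.73).

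The EB array shared low probe sets with ORMES6. Of 23 probe sets over 3 log2 units lower in 1 line than in each of the other 4, 5 were low in ORMES6, and on all 5 the EB array was also low, within 1.5 units of ORMES6 or below it, against 1 of the 18 probe sets low in another line (Fisher's exact test, two-sided, p = 0.000178). They were probe sets of RPL7L1 (ORMES6 4.68, EBs 4.19, lowest other line 9.50), ZNF167 (4.73, 4.34 and 8.50), LZIC (4.60, 4.04 and 7.66) and C14orf169 (5.53, 4.59 and 8.94) and a probe set without a symbol (9.30, 7.89 and 12.76). The labels used here do not name the line behind the EB pool, and these values are consistent with a pool made from ORMES6 cells, as a hypothesis. The spike level shared by the EB array with ORMES6 A and B is argued against as the whole cause, since with the high-spike ES arrays only (replicate C for ORMES6) the EB array was low on 4 of 4 probe sets low in ORMES6 alone, 3 of them among the 5, and on 2 of 18 low in another line (Fisher's exact test, two-sided, p = 0.00205). For LZIC and C14orf169, which were not in that selection, it stays open. Both Fisher tests count probe sets as independent units, which they are not. In ORMES9, SNRPN and CAP1 each gave more than 1 probe set, and IPW and MAGEL2 lie in the region of SNRPN. The selections of both tests overlap and share 1 EB array, so the p-values overstate the evidence. If the hypothesis holds, the comparison with EBs also carries differences between ORMES6 and the other lines. A fit with the ORMES6 arrays alone takes its error from the replicates and not from the lines. Set against the 3 ORMES6 arrays alone, the EB array had 540 probe sets lower and 1142 higher than the ES cells.

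The deposited detection calls headed as those of the EB array did not follow the EB signals. Present and Absent probe sets differed by 0.08 in mean log2 signal and 448 of 881 EB signals over 3000 were called Absent, where on the other arrays with deposited detection values 0 such signals were. The authors' deposited table of 3200 probe sets, 3064 of them lower in ORMES6 A by the deposited ratio, lists only probe sets with a Present call in a column equal to these calls. Of its probe sets with values here, 93% were lower in the mean of the 5 lines than in EBs. The deposited ratio used the same EB array, and ORMES6 A is part of that mean. This share therefore says nothing about whether the calls are sound.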
